A study of Mus musculus with 2 samples.

How the data were processed

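Single-cell RNA sequencing was carried out on embryonic mouse hearts at embryonic day 15.5, with 1 library from control heart and 1 from heart with a conditional knockout (cKO) of Ino80, the ATPase subunit of the INO80 chromatin-remodelling complex. Per the labels, a droplet-based 3′ kit was used. The design text speaks of endothelial cells, but the deposited matrices held transcripts of all major heart cell types. Per the submitters' processing notes, reads were processed with Cell Ranger 2.0.0 and the genome build was mm10. The annotation version is not given in the sources used here. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Whether cells or doublets were removed beyond the cell calling of the matrices is not stated in the sources used here.

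The control library held 518 barcodes and 7790382 UMIs, with a median of 14102 UMIs per barcode. The cKO library held 576 barcodes and 10364165 UMIs, with a median of 17625 per barcode. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 446 control and 523 cKO cells. Of the 72 control barcodes left out, 34 failed on genes, 50 on mitochondrial share and 12 on both. Of the 53 cKO barcodes left out, 11 failed on genes, 48 on mitochondrial share and 6 on both. By nearest neighbours, 32 of the control and 37 of the cKO barcodes left out resembled cardiomyocytes, so the mitochondrial limit removed part of that cell type from both libraries.

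Kept cells of both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes among those found in at least 3 cells, 30 principal components, 15 neighbours and the Leiden method at resolution 1 were used (scanpy 1.11.5, python-igraph 0.11.9, scikit-learn 1.9.0). Mitochondrial, ribosomal protein, haemoglobin, sex-linked and cell-cycle genes and Ino80 were left out of the variable genes. Cluster names came from 17 marker lists. A marker counted for a cluster where it reached 20 CPM (UMIs scaled to a common library total) and 5 times the median over clusters; an endothelial name needed 6 of the 12 pan-endothelial markers and any other name needed 3 markers. Those limits were set after the data had been seen. Endothelial-like clusters were split by which list had the larger share of high markers, the endocardial or the coronary capillary one. The first kind was called Npr3-high, with clusters 6, 8 and 13, and the second Fabp4-high, with cluster 2. Npr3 itself was not required, and it stood among the top-ranked genes of cluster 6 but not of clusters 8 and 13. A cluster that mixed erythroid and immune markers stayed unnamed. Doublets were not removed in the main analysis. Scrublet called 1 control and 5 cKO doublets, and their removal was an alternative setting.

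UMIs were summed per library and cell class and divided by the sum over all genes, as CPM. Ratios are given as folds of CPM with exact conditional binomial intervals, and sums with exact Poisson intervals. Log2 ratios are of CPM with a pseudocount of 10 added, which understates the difference of low genes. Shares of cells have exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error only. With 1 library per group, no test between the conditions was possible, no p-value is given, and every difference is one between 2 libraries without a replicate check. How many embryos entered each library is not given in the sources used here.

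The genes to be named, the gene lists, the markers and most alternatives were fixed before the data were examined. Among genes with at least 20 CPM in either library, the 12 with the largest and the 12 with the smallest log2 ratio in endothelial-like cells were named, together with Ino80, 4 angiocrines (secreted endothelial factors) remembered from the study, and the 2 highest and 2 lowest members of each list. In each endothelial subclass with at least 40 cells per library, the 5 highest and 5 lowest genes with at least 50 CPM were named. The same rule was applied to fibroblast-like, mural-like and cardiomyocyte-like cells after the data had been seen. Of the genes so ranked in fibroblast-like cells, only part are named below. Sex-linked, mitochondrial, haemoglobin and ribosomal protein genes, gene models with Gm numbers or names ending in Rik, and cardiomyocyte, erythroid and macrophage markers were left out of that ranking. In endothelial-like cells Xist was the only gene left out of it that lay within the range of the named genes. In cardiomyocyte-like cells the cardiomyocyte marker Nppa lay among the highest, and 13 genes left out lay among the lowest, all of them gene models or a ribosomal protein pseudogene. In fibroblast-like cells Rpl29 lay among the highest and 4 gene models or ribosomal protein pseudogenes among the lowest, and in mural-like cells the cardiomyocyte marker Actc1 lay among the highest.

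The 18 lists covered the INO80 complex, S phase, G2/M, the p53 response, the study angiocrines, other secreted factors, interferon response, hypoxia response, the Notch pathway, tip cells and sprouting, the BMP and TGF-beta pathway, shear stress response, epithelial-to-mesenchymal transition and matrix, lipid handling and capillary genes, oxidative phosphorylation, dissociation stress, imprinted growth genes, and sex-linked genes. The list symbols Ccn1, Ccn2, Rian and Zac1 did not match a gene in the deposited matrices. Each list's median log2 ratio has an interval from 1000 Poisson redraws of its counts. Each median was also placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. That percentile describes these 2 libraries. To compare shares of cells with a transcript, every cell was thinned to 3000 UMIs.

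Alternatives covered edgeR 4.0.16 TMM scaling (R 4.3.3), totals without mitochondrial, ribosomal protein and haemoglobin genes, equal weight per cell, pseudocounts of 1 and 50, no filter or a minimum of 50 CPM for genes, no cell filter or a stricter one (1000 genes and 5% mitochondrial UMIs), doublet removal, equal weight of the endothelial subclasses, thinning, and other clustering settings. Leaving out cluster 13, using cells with Xist or with Y-linked transcripts alone, clustering without genes that differed between libraries, repeating the thinning in 20 draws, and equal weight per cell in the depth tests, which gives each gene the level expected over draws, were added after the data had been seen. An early version thinned each cell class separately, so that values of subclasses did not add up. It was replaced by 1 draw over all cells, after its values had been seen.

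The procedure was tested on simulated counts for the 6196 genes of the endothelial-like comparison. Counts were Poisson draws from pooled levels, the model that the intervals assume. Spread between cells was not simulated, so the rates below hold for counting error only. Intervals covered the true ratio for 95.6% of unchanged genes. They excluded a ratio of 1 for 100% of genes changed 2-fold or 4-fold in either direction, for 88% of genes raised 1.5-fold and for 72% of genes lowered by that factor. Of 200 simulated unchanged lists, 96.5% fell inside the central 95% of the random lists. Gene positions were taken from GENCODE on the same build, in which 27645 of the 27998 gene identifiers were found. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.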

Results

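Hearts of mouse embryos were profiled by single-cell RNA sequencing, with 1 control library of 446 kept cells and 1 library from an Ino80 conditional knockout (cKO) of 523 kept cells. The series title places the study in the question of how factors secreted by endocardium and endothelium act on cardiomyocytes. Kept cells held 7158293 UMIs in the control and 9647174 UMIs in the cKO library. There are no replicates, so each difference below is one between 2 libraries, and each interval covers counting error only.

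Ino80, the targeted gene (ENSMUSG00000034154, chromosome 2, 119373042 to 119477687 in mm10), was lower in endothelial-like cells of the cKO library. It had 36 UMIs, or 14.6 CPM, in the control and 18 UMIs, or 5.17 CPM, in the cKO library, a ratio of 0.353 (95% interval 0.189 to 0.639). In fibroblast-like cells the values were 7.47 and 7.89 CPM, and in mural-like cells, the contractile cells around vessels, 11.9 and 11.6 CPM. The labels name neither the deleted exons nor the Cre driver, and a 3′ tag may come from outside a deleted part, so these values check the labels only weakly. Among the measured members of the INO80 complex list, Uchl5 was 1.82-fold higher (1.45 to 2.29) and Ruvbl2 1.54-fold higher (1.23 to 1.96). Ino80 itself lay under the minimum of 20 CPM in both libraries and is not among the 11 measured members. Of these 11 members 1 was at least 1.5-fold higher on the log2 scale and 0 lower, with a median log2 ratio of 0.11 (0.03 to 0.29) at percentile 73.7 of random lists. With mitochondrial, ribosomal protein and haemoglobin genes left out of the total, the median was 0.026 over 14 members and 0.061 over the same 11.

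Endothelial-like cells made up 152 of 446 control cells, or 34.1% (29.7 to 38.7), and 172 of 523 cKO cells, or 32.9% (28.9 to 37.1). Npr3-high cells, in whose clusters 6 to 9 of the 12 endocardial markers were high, made up 65.1% of control (57.0 to 72.7) and 70.3% of cKO endothelial-like cells (62.9 to 77.1). The other endothelial-like cells formed the Fabp4-high cluster, led by the coronary capillary markers Fabp4 and Gpihbp1. The intervals of both shares overlapped, and no difference was detectable at this depth. Clustering without the 844 genes that differed 1.5-fold between the libraries gave Npr3-high shares of 64.3% and 69.8%. Different clusters held most Npr3-high cells in each library: cluster 6 held 76 control and 9 cKO cells, cluster 8 held 23 and 95, and cluster 13 held 0 and 17. Most cells of each library also lay in different Npr3-high clusters without a cell filter (92 control and 19 cKO cells in one, 10 and 107 in the other), with a stricter filter, without called doublets, with cell-cycle genes kept and at resolution 2. At resolution 0.5 a single cluster held 99 control and 104 cKO cells beside the one of 17 cKO cells, and without the 844 genes the Npr3-high clusters held 69 and 67, and 30 and 53 cells. The 0 control cells in cluster 13 allow a share of up to 3.03% of control Npr3-high cells, taken as 3 of 99 cells.

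The libraries also differed in ways that are not the genotype label. Xist without Y-linked transcripts was found in 59.9% of control endothelial-like cells (51.6 to 67.7) and 33.1% of cKO cells (26.2 to 40.7), and Y-linked transcripts without Xist in 25.7% and 50.6%. In the list of sex-linked genes Xist, the long RNA of the inactive X chromosome, had 857 and 330 CPM, and the 4 measured members had a median log2 ratio of -0.16 (-0.41 to 0.02). Median UMIs per endothelial-like cell were 14193 in the control and 18616 in the cKO library. Mitochondrial UMIs had a median of 3.39% and 4.04% of each such cell, and ribosomal protein UMIs 25.1% and 20.7%. Erythroid markers had 10149 CPM over all kept control cells and 20095 CPM over all kept cKO cells. These sums depend on the cell filter. It left out 34 control and 11 cKO barcodes that by nearest neighbours resembled the unnamed cluster of erythroid and immune markers. With no cell filter, a cluster led by haemoglobin genes held 25 control and 17 cKO cells. Within endothelial-like cells the erythroid list had a median log2 ratio of -0.02 (-0.13 to 0.12) and the cardiomyocyte list -0.14 (-0.25 to 0.01).

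In endothelial-like cells Cdkn1a, the cyclin-dependent kinase inhibitor p21, stood highest in the cKO library relative to the control. Its level was 35.3 CPM in the control and 197 CPM in the cKO library, 5.59-fold higher (4.47 to 7.07). Isg15, an interferon-induced ubiquitin-like protein, was 5.41-fold higher (3.95 to 7.59), and Tgfbi, a secreted matrix protein induced by TGF-beta, 3.72-fold higher (3.10 to 4.49). Cytl1, a secreted cytokine-like protein and endocardial marker, was lowest by log2 ratio, with 157 CPM in the control and 16.4 CPM in the cKO library, 9.60-fold lower (7.26 to 12.9). Stmn2 followed with 62.9 and 2.58 CPM, 24.4-fold lower (12.5 to 54.3).

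The other 9 highest of the 12 were Pbk, Rarres2, Tk1, Ifi27l2a, Top2a, Ccng1, Spc25, Nusap1 and Mif. Pbk, Tk1, Top2a, Spc25 and Nusap1 act in DNA synthesis or mitosis, and their folds lay between 3.25 for Top2a (2.68 to 3.97) and 5.05 for Pbk (3.55 to 7.37). Ccng1, a p53 target, was 3.62-fold higher (2.61 to 5.11). Mif, a cytokine, was abundant at 431 and 1094 CPM, 2.54-fold higher (2.37 to 2.72). For Ifi27l2a, at 4.74-fold, 1 cell supplied 27.6% of the UMIs of the cKO library. The other 10 lowest were Mustn1, Col15a1, Aqp1, Cldn5, Aplnr, Jam2, Tmem255a, Ccdc85b, Enpp6 and Ly6c1. Cldn5, a tight junction protein of endothelium, had 289 and 89.5 CPM, 3.22-fold lower (2.82 to 3.69). Aplnr, the apelin receptor, was 3.54-fold lower (2.86 to 4.40), and Aqp1, a water channel, 3.74-fold lower (2.998 to 4.69). The median log2 ratio over the 6196 compared genes was 0.06. Of the 24 ranked genes 7 were still among the ranked ones when each cell was thinned to 3000 UMIs, 12 in cells with Xist alone and 13 in cells with Y-linked transcripts alone.

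**Figure D1:**
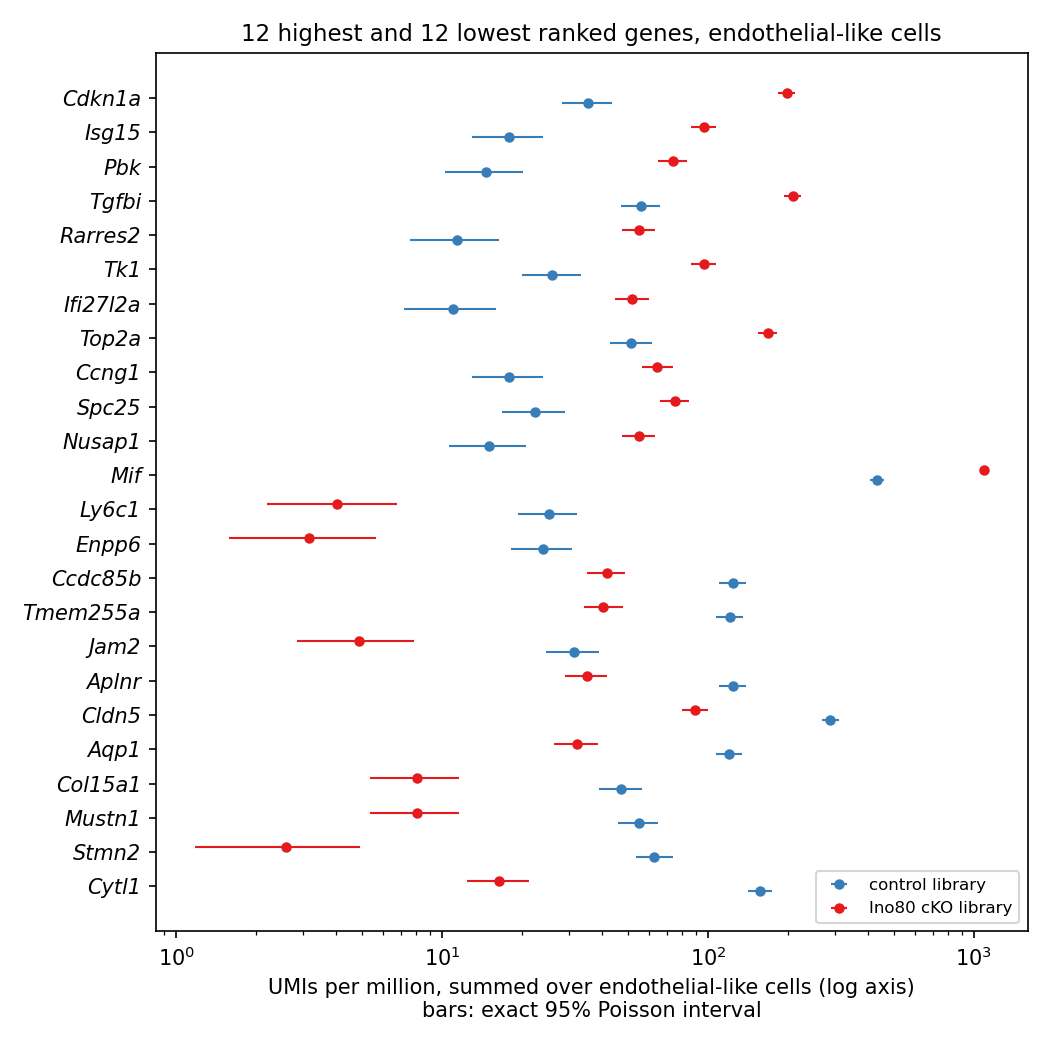
Level of the 12 highest and 12 lowest ranked genes in endothelial-like cells, in CPM on a log axis, with 1 point per library (blue, control; red, cKO) and bars for the exact 95% Poisson interval. Cdkn1a had 35.3 CPM in the control and 197 CPM in the cKO library, and Cytl1 157 and 16.4 CPM.

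In mm10 Cdkn1a (ENSMUSG00000023067) lies on chromosome 17, 29090976 to 29100727, and Cytl1 (ENSMUSG00000062329) on chromosome 5, 37735519 to 37739820. Isg15 (ENSMUSG00000035692) lies on chromosome 4, 156199424 to 156200818, and Tgfbi (ENSMUSG00000035493) on chromosome 13, 56609523 to 56639562. Igfbp3 (ENSMUSG00000020427) lies on chromosome 11, 7206086 to 7213923, and Adm (ENSMUSG00000030790) on chromosome 7, 110627661 to 110629820. All are protein-coding genes, and the tags were counted per gene, so the exon or untranslated region they fall in is not resolved.

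The 4 angiocrines remembered from the study were Tgfbi, Isg15, Igfbp3 and Adm, and 3 of the 4 were at least 1.5-fold higher in endothelial-like cells of the cKO library. Igfbp3, a binding protein for insulin-like growth factors, had 351 and 404 CPM, 1.15-fold higher (1.06 to 1.26). Adm, the vasodilator peptide adrenomedullin, had 10.96 and 30.1 CPM, 2.75-fold higher (1.79 to 4.37). Their median log2 ratio was 1.33 (1.12 to 1.55), at percentile 100. The study may have chosen these genes on these libraries, so the list is not independent evidence. Adm is also in the hypoxia and tip cell lists, Isg15 in the interferon list and Tgfbi in the BMP and TGF-beta list. In cells with Y-linked transcripts alone, the direction turned for the gene Igfbp3 (log2 ratio -1.30) and for the gene Adm (-0.26), and the list median was 0.56; in cells with Xist alone it was 1.61. Among the other secreted factors 1 of 18 was higher and 4 were lower, with a median of 0.03 (-0.12 to 0.08) at percentile 35.5, and 0.12 in cells with Y-linked transcripts alone. Edn1, the peptide endothelin 1, was 1.97-fold higher (1.54 to 2.52). The chemokine Cxcl12 was 3.32-fold lower (2.07 to 5.47), with 1 cell supplying 32.8% of its control UMIs and a log2 ratio of 0.14 in cells with Xist alone. Igfbp7 was 2.37-fold lower (1.85 to 3.04), with a log2 ratio of 0.46 in cells with Y-linked transcripts alone.

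In endothelial-like cells of the cKO library most G2/M genes and part of the S phase genes were higher. Of 40 measured G2/M genes 30 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.82 (0.75 to 0.89), and of 37 S phase genes 15 were higher and 0 lower, with a median of 0.53 (0.45 to 0.62). Both medians lay at percentile 100. Tyms, the thymidylate synthase, was 2.51-fold higher (2.08 to 3.04) and Ccne2, a cyclin of the G1/S transition, 2.86-fold higher (2.09 to 3.97). Without the 17 cells of cluster 13, which came from the cKO library, the medians were 0.25 for S phase and 0.44 for G2/M. In cells with Y-linked transcripts alone they were 0.85 and 1.41, and the S phase median was 0.34 in cells with Xist alone. After thinning to 3000 UMIs, at least 3 S phase UMIs were found in 39.5% of control cells (31.6 to 47.7) and 59.3% of cKO cells (51.6 to 66.7). For G2/M these shares were 61.2% (52.95 to 69.0) and 77.9% (71.0 to 83.9). Unthinned, they were 90.1% and 98.3% for S phase and 98.0% and 100% for G2/M. Many cells lay near that limit: 49 control and 45 cKO cells had 2 or 3 S phase UMIs, and 51 and 38 had 2 or 3 G2/M UMIs. In cardiomyocyte-like cells at the same depth the S phase shares were 37.8% and 48.5% and the G2/M shares 58.5% and 72.2%, also higher in the cKO library. Cell-cycle genes were not low in these cells, with Top2a at 111 and 113 CPM, so their shares do not gauge free RNA. The part that free RNA takes in the endothelial-like shares is open.

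Of 14 measured members of the p53 response list 7 were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 0.69 (0.54 to 0.87) at percentile 100. Besides Cdkn1a and Ccng1, the members higher by that size were Bax (1.17), Zmat3 (1.14), Phlda3 (1.12), Rps27l (1.02) and Aen (0.94), as log2 ratios, named after their values were seen. Gadd45g was 1.77-fold lower (1.33 to 2.35), and Btg2 1.43-fold lower (1.22 to 1.68), with a log2 ratio of 0.15 in cells with Y-linked transcripts alone. A Cdkn1a UMI was found after thinning in 5.26% of control endothelial-like cells (2.30 to 10.1) and 27.3% of cKO cells (20.8 to 34.6). In cardiomyocyte-like cells thinned to the same depth it was found in 7.32% and 13.4%, with median depths before thinning of 7941 and 8464 UMIs per cell. Unthinned, the endothelial-like shares were 16.4% and 50.6%. Without a filter on low genes the median of this list was 0.26 over 27 genes, and with a minimum of 50 CPM it was 1.02 over 9. Without mitochondrial, ribosomal protein and haemoglobin genes in the total it was 0.40 over 16 genes. Over the 14 genes of the main setting it was 0.69 with that total, so the fall came from added members.

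Interferon response genes were higher in 7 of 14 and lower in 0, with a median of 0.57 (0.43 to 0.80) at percentile 100. This median was 0.37 with the subclasses weighted equally, 0.86 after thinning, 1.15 at a minimum of 50 CPM and 1.22 in cells with Xist alone. Over the members of the main setting it was 0.67 after thinning, 0.57 at that minimum and 0.84 in cells with Xist alone. Isg15, which is also 1 of the study angiocrines, led this list. Bst2, Rtp4, Oasl2 and Ifitm3 had log2 ratios of 1.19, 1.27, 1.26 and 1.11, and were named after their values were seen. After thinning, Isg15 UMIs were found in 3.95% of control (1.46 to 8.39) and 13.4% of cKO endothelial-like cells (8.67 to 19.4), and in 0 of 82 control and 0 of 97 cKO cardiomyocyte-like cells, whose intervals reach 4.40% and 3.73%. Unthinned, the endothelial-like shares were 13.8% and 38.4%. Hypoxia response genes were higher in 9 of 23 and lower in 1, with a median of 0.53 (0.45 to 0.63) at percentile 100. Mif and Higd1a led this list, and Higd1a, a mitochondrial protein, was 2.22-fold higher (1.95 to 2.53). Ndrg1 was 2.70-fold lower (1.98 to 3.71). Oxidative phosphorylation genes had a median of 0.23 (0.19 to 0.26) over 57 members, at percentile 99.6, and 2 were at least 1.5-fold higher.

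Of 12 Notch pathway genes measured in endothelial-like cells, 5 were lower in the cKO library and 0 higher, with a median of -0.36 (-0.50 to -0.16) at percentile 0. The Notch median was -0.16 in cells with Xist alone, -0.70 in cells with Y-linked transcripts alone and -0.66 at a minimum of 50 CPM. Over the members of the main setting these values were -0.16, -0.40 and -0.36. In Npr3-high cells the Notch median was -0.07 (-0.28 to 0.13) over 8 genes. Sox17, an arterial transcription factor, was 1.88-fold lower (1.43 to 2.48). Of 9 lipid handling and capillary genes 4 were lower and 1 higher, with a median of -0.49 (-0.65 to -0.30) at percentile 0. Rgcc was 3.15-fold lower (2.36 to 4.24) and Gpihbp1, the capillary anchor of lipoprotein lipase, 2.02-fold lower (1.77 to 2.31), while Angptl4, an inhibitor of that lipase, was 3.45-fold higher (2.36 to 5.18). By subclass the median of this list was 0.65 (0.35 to 0.93) over 5 members in Npr3-high cells and -0.40 (-0.50 to -0.22) over 10 in Fabp4-high cells, and with the subclasses weighted equally it was -0.0055. After thinning it was -0.20, and in cells with Y-linked transcripts alone -0.25. Coronary capillary markers, among them Rgcc, Gpihbp1, Aplnr and Aqp1, were lower in 7 of 10, with a median of -0.80 (-0.88 to -0.65), and arterial markers in 4 of 8, with a median of -0.52 (-0.63 to -0.30). Both medians are of sums over the 2 subclasses. The Fabp4-high cluster supplied 1112256 of 2463158 UMIs in the control and 1310617 of 3484125 in the cKO library, a smaller part that also enters them. Pan-endothelial markers had a median of -0.04 (-0.12 to 0.03).

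Shear stress genes had a median of -0.17 (-0.31 to -0.05) at percentile 1.10, and -0.36 with the subclasses weighted equally, with 5 of 14 lower and 1 higher, and Cav1, the caveolar protein, was 2.09-fold lower (1.96 to 2.23). Genes of epithelial-to-mesenchymal transition and matrix had a median of -0.19 (-0.26 to -0.08), with 3 of 21 lower, among them Cdh11, 2.02-fold lower (1.79 to 2.28). That median was -0.0089 in cells with Xist alone, -0.048 with no filter on low genes and -0.32 after thinning. Over the members of the main setting these values were 0.057, -0.19 and -0.31. Genes of the BMP and TGF-beta pathway had a median of -0.19 (-0.27 to -0.003), with 3 of 19 lower and 1 higher, Tgfbi, a study angiocrine, and after thinning it was -0.32. The tip cell list had a median of 0.10 (0.03 to 0.21) at percentile 63.9, and 0.22 in cells with Xist alone. Its direction turned after thinning, at -0.055. In cells with Y-linked transcripts alone the median was -0.013, but 0.054 over the members of the main setting. Dissociation stress genes, which respond to tissue digestion, had a median of -0.24 (-0.32 to -0.11), which turned to 0.15 in cells with Y-linked transcripts alone and was -0.49 in cells with Xist alone. Imprinted growth genes had a median of -0.25 (-0.34 to -0.16), which turned to 0.18 in cells with Xist alone and was -0.39 in cells with Y-linked transcripts alone, -0.40 with equal weight per cell and -0.15 with no filter on low genes. In this list Dlk1 was 1.99-fold higher (1.79 to 2.21). A pseudocount of 50 brought the S phase median to 0.28, G2/M to 0.43, p53 to 0.38, the angiocrines to 0.75, interferon to 0.35, hypoxia to 0.34 and lipid handling to -0.26.

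**Figure D2:**
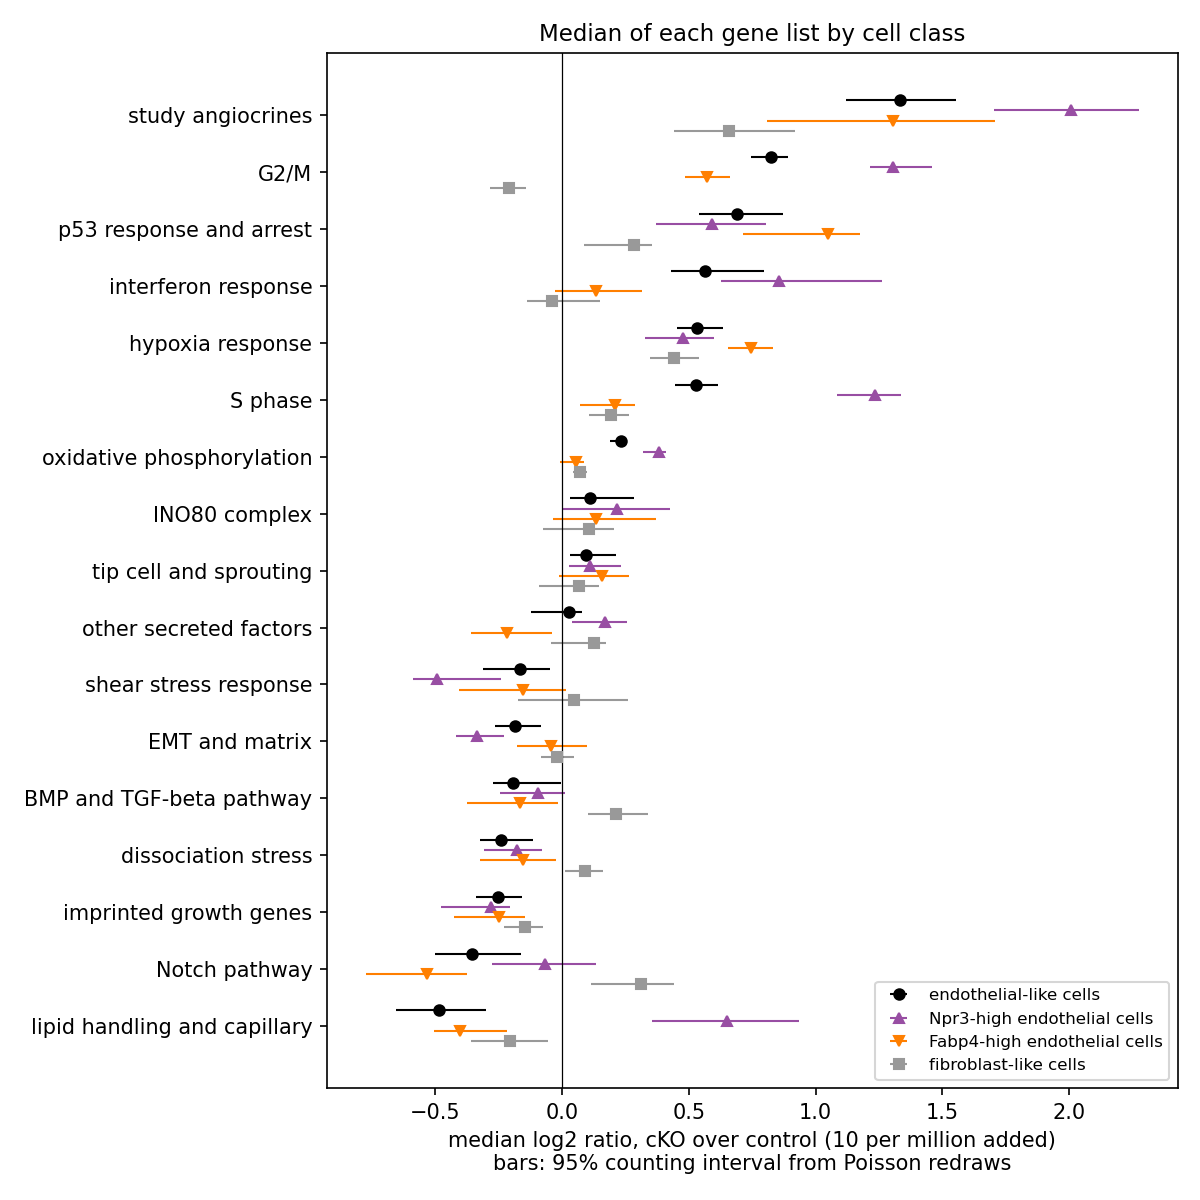
Median log2 ratio of each gene list, cKO over control with 10 CPM added, on the horizontal axis, with 1 symbol per cell class and bars for the 95% counting interval. In endothelial-like cells the medians run from -0.49 for lipid handling and capillary genes to 1.33 for the study angiocrines, and the hypoxia list lies above 0 in each class plotted.

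In the Npr3-high cells, where clusters 8 and 13 held most cKO cells and cluster 6 most control cells, DNA replication and mitosis genes were highest. Top2a, a topoisomerase, had 8.88 CPM in the control and 144 CPM in the cKO library, 16.2-fold higher (9.15 to 31.7), and Tk1, the thymidine kinase, 5.18 and 88.3 CPM. Rrm2, Pbk and Ube2c completed the 5 highest, with 3, 3 and 14 UMIs in the control. The 74 measured S phase and G2/M genes had a joint median of 1.29 (1.19 to 1.37), and without cluster 13 it was 0.34 (0.28 to 0.47). Pbk had a log2 ratio of -0.067 and Ube2c of -0.065 without that cluster. Several of these genes also led the clusters: Cytl1 led cluster 6, Isg15 cluster 8, and Tk1, Pbk and Top2a cluster 13. The 5 lowest were Cytl1, 10.9-fold lower (8.21 to 14.6), Stmn2, Mustn1, Ndufa4l2 and AU021092. Igfbp3 had 48.9 and 227 CPM, 4.64-fold higher (3.59 to 6.10), Isg15 was 6.38-fold higher (4.40 to 9.54), and Cdkn1a 2.77-fold higher (1.97 to 3.97). Interferon response genes were higher in 9 of 15, with a median of 0.86 (0.63 to 1.26).

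In the Fabp4-high cluster, with 53 control and 51 cKO cells, Cdkn1a was highest. It had 40.5 and 382 CPM, 9.45-fold higher (6.96 to 13.1), and Ccng1 had 13.5 and 92.3 CPM, 6.85-fold higher (3.99 to 12.6). The p53 list had a median of 1.05 (0.71 to 1.18), with 9 of 16 members higher and 2 lower. Nts, with 1 cell supplying 47.7% of its cKO UMIs, Igfbp5 and Ppp1r14a completed the 5 highest. The 5 lowest were Stmn2, with 1 cell supplying 41.6% of its control UMIs, Col15a1, 9.88-fold lower (5.54 to 19.1), Aplnr, 4.03-fold lower (3.16 to 5.20), Tmem176b and Aqp1. Hypoxia response genes were higher in 16 of 26 and lower in 1, and Notch genes lower in 6 of 13, with medians of 0.75 (0.66 to 0.83) and -0.53 (-0.77 to -0.37). Of 42 G2/M genes 20 were higher in this cluster, with a median of 0.57 (0.49 to 0.66), and of 39 S phase genes 5, with a median of 0.21 (0.07 to 0.29) that turned to -0.18 in cells with Xist alone. Of 7 interferon response genes 0 were higher and 0 lower, with a median of 0.13 (-0.03 to 0.32). Mitochondrially encoded genes were higher in 6 of 12 there, with a median of 0.58 (0.53 to 0.65), and the median mitochondrial share per cell was 2.502% and 3.50%. Adm was 3.10-fold higher (1.99 to 4.99), with a log2 ratio of -0.18 in cells with Y-linked transcripts alone. Igfbp3 had 717 and 699 CPM, and Isg15 11.7 and 14.5 CPM, differences within counting error. Whether the subclasses differed from each other was not tested.

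Cardiomyocyte-like cells numbered 83 in the control and 97 in the cKO library, after the mitochondrial limit had removed further cells of this kind from both. Of these, 66 control and 74 cKO cells lay in clusters 7 and 10. Median mitochondrial shares there were very low, at 0.099% and 0.089% in cluster 7 and 0.096% and 0.116% in cluster 10. In cluster 12 they were 8.33% and 7.14%. Median UMIs were 5780 and 6001 in cluster 7, and 21956 and 20727 in cluster 12. The values below therefore rest on cells of unlike quality. Nppa, the atrial natriuretic peptide gene expressed in atrial and trabecular myocardium (chromosome 4, 148000722 to 148002079), had 204 and 1327 CPM, 6.50-fold higher in the cKO library (5.56 to 7.65), with 1 cell supplying 27.6% of its cKO UMIs. With no cell filter it was 8.23-fold higher (7.12 to 9.55), and within cluster 12 it was 5.002-fold higher (2.94 to 9.07). Ankrd1, a stretch-responsive protein of the sarcomere, was 2.34-fold higher (2.12 to 2.58). Nppb was 2.79-fold higher (2.14 to 3.68), with 1 cell supplying 50.7% of its control UMIs. Within clusters 7 and 10 Nppb was 6.93-fold higher (4.28 to 11.8), and within cluster 12 the ratio was 1.37 (0.973 to 1.95). Of the myosin heavy chains, Myh7 had a ratio of 0.998 (0.943 to 1.06) and Myh6 of 0.683 (0.560 to 0.831). Sln, expressed mainly in atrial myocardium, had 39 UMIs in the control, 38 of them in 1 cell, and 0 in the cKO library. Nppa, Myh6, Myh7 and Sln were chosen after their values were seen. By the ranking rule the 5 highest genes were Nppb, Slc16a3, Krt19, Ankrd1 and Phlda1, and the 5 lowest Fabp3-ps1, Runx1t1, Ramp1, Wdr82 and Fn1. The hypoxia list was higher in 11 of 20, with a median of 0.62 (0.42 to 0.65). How many atrial and ventricular cells each library holds is not given by the labels.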

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

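The limits that defined opposite directions, at least 50 CPM in either library in both subclasses and 1.5-fold each way on the log2 scale with both counting intervals excluding 1, were chosen only after the result was seen. Of 2514 genes compared in both endothelial subclasses, 5 differed in opposite directions between the libraries. With 1 library per group the difference between the subclasses was not tested, and clusters 6, 8 and 13 hold different shares of the Npr3-high cells in each library.

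Nts, the neurotensin gene, had 94.8 CPM in the control and 31.3 CPM in the cKO library in Npr3-high cells, and 45.9 and 203 CPM in Fabp4-high cells, a difference of log2 ratios of -3.27, with 1 cell supplying 34.4% of its control UMIs in the former and 1 cell 47.7% of its cKO UMIs in the latter. Tcf15, a transcription factor of capillary endothelium, had 51.8 and 133 CPM in Npr3-high cells and 358 and 179 CPM in Fabp4-high cells, a difference of 2.17. For Ly6e the values were 48.1 and 90.2 CPM, and 205 and 105 CPM, a difference of 1.68. Gsta4, a glutathione transferase, had 142 and 86.0 CPM, and 22.5 and 51.9 CPM, a difference of -1.59. Gatm, an enzyme of creatine synthesis and an endocardial marker in the lists, had 121 and 65.8 CPM, and 52.1 and 89.3 CPM, a difference of -1.47.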

How the results depend on the processing

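The settings without cluster 13, with Xist or Y-linked cells alone and with genes left out of the clustering were chosen only after the result was seen. No paired analysis was possible because each group had 1 library. Of the values for comparisons, 254 stayed within their counting interval (for the number of shared ranked genes, within a factor of 1.5), 81 moved further and 4 reversed; of those for named genes, 1065 stayed, 300 moved and 9 reversed, and for the lists in the subclasses 387, 80 and 9. TMM, cell filters and doublet removal moved no comparison value beyond its interval, and all shares of endothelial-like and Npr3-high cells stayed within theirs. Scaling moved the median of all genes by at most 0.05 in size (-0.05 without mitochondrial, ribosomal protein and haemoglobin genes). List medians under filters, subsets, thinning and other totals also change because other members pass the minimum. The p53 move without mitochondrial, ribosomal protein and haemoglobin genes in the total was of this kind, with 0.69 over the members of the main setting. So were the moves of list medians at a minimum of 50 CPM and with no filter on low genes, since those medians were unchanged over the members of the main setting. The cause of the remaining moves was not tested. Counts limit low genes most, and thinning to 3000 UMIs adds the noise of the draw.

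Values below are median log2 ratios in endothelial-like cells unless said otherwise. Without mitochondrial, ribosomal protein and haemoglobin genes in the total, the INO80 complex was at 0.026, the p53 list 0.40, matrix genes -0.27 and oxidative phosphorylation 0.18. Over the members of the main setting these were 0.061, 0.69, -0.25 and 0.18. Other secreted factors reversed to -0.013 in Npr3-high cells, but were at 0.097 over the members of the main setting. With equal weight per cell S phase was at 0.65 and imprinted genes at -0.40. With a pseudocount of 1, S phase was at 0.67, G2/M 0.99, angiocrines 1.63 and Ino80 -1.34, and 14 of the 24 ranked genes were shared. With a pseudocount of 50, S phase was at 0.28, G2/M 0.43, p53 0.38, angiocrines 0.75, interferon 0.35, hypoxia 0.34, lipid handling -0.26 and Ino80 -0.23, with 15 ranked genes shared.

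With no filter on low genes p53 was at 0.26, interferon 0.41, matrix -0.048 and imprinted genes -0.15, and other secreted factors reversed to -0.10 in Npr3-high and to 0.0082 in Fabp4-high cells. At a minimum of 50 CPM p53 was at 1.02, angiocrines 1.73, other secreted factors 0.10, interferon 1.15, hypoxia 0.64 and Notch -0.66. With subclasses weighted equally S phase was at 0.70, G2/M 0.98, angiocrines 1.10, interferon 0.37, shear stress -0.36 and lipid handling -0.0055, and the gene Col3a1 reversed to -0.059. Thinned to 3000 UMIs, p53 was at 0.48, angiocrines 0.97, interferon 0.86, hypoxia 0.65, BMP and TGF-beta -0.32, matrix -0.32 and lipid handling -0.20, tip cell genes reversed to -0.055, and 7 ranked genes were shared. Over the members of the main setting thinned interferon was at 0.67, hypoxia 0.62 and matrix -0.31. Without cluster 13 S phase was at 0.25, G2/M 0.44 and hypoxia 0.64, and Pbk reversed to -0.067 and Ube2c to -0.065 in Npr3-high cells.

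In cells with Xist alone S phase was at 0.34, angiocrines 1.61, interferon 1.22, hypoxia 0.38, Notch -0.16, tip cell genes 0.22, matrix -0.0089 and dissociation stress -0.49, with 12 ranked genes shared. Over the members of the main setting S phase was there at 0.35, interferon 0.84, hypoxia 0.31 and matrix 0.057. There imprinted genes reversed to 0.18, and to 0.028 in Npr3-high cells, the gene Cxcl12 to 0.14, and in Fabp4-high cells S phase to -0.18 and other secreted factors to 0.032. In cells with Y-linked transcripts alone S phase was at 0.85, G2/M 1.41, angiocrines 0.56, other secreted factors 0.12, hypoxia 0.43, Notch -0.70, lipid handling -0.25 and imprinted genes -0.39, with 13 ranked genes shared. Over the members of the main setting S phase was there at 0.77, G2/M 1.37 and Notch -0.40. There tip cell genes reversed to -0.013, but were at 0.054 over the members of the main setting. Dissociation stress also reversed there, to 0.15 (0.28 in Npr3-high and 0.0498 in Fabp4-high cells). The gene Igfbp3 reversed to -1.30, Adm to -0.26, Btg2 to 0.15 and Igfbp7 to 0.46, and in Fabp4-high cells Adm and the angiocrine median to -0.18.

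The shares of cells with cell-cycle UMIs moved with depth and minimum, and were higher in the cKO library under each setting run. Unthinned, the control and cKO shares were 90.1% and 98.3% for S phase and 98.0% and 100% for G2/M. Thinned to 2000 UMIs they were 26.3% and 45.9%, and 43.4% and 68.0%. At a minimum of 2 UMIs they were 59.9% and 74.4%, and 80.3% and 89.0%. At a minimum of 5 they were 19.7% and 39.0%, and 29.6% and 54.1%.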

Other observations

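The 3 patterns weighed in this part were chosen after the list medians had been seen, and of the tests, those of a shift of the whole library for p53 genes, of repeated thinning draws and of equal weight per cell were chosen only after the result was seen.

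In fibroblast-like cells, 99 in the control and 134 in the cKO library, Meox1, a homeobox transcription factor, had 32.5 and 125 CPM, 3.86-fold higher in the cKO library (2.93 to 5.15), and the chemokine Ccl2 98.1 and 259 CPM, 2.64-fold higher (2.24 to 3.12). Tgfbi was 2.32-fold higher there (1.88 to 2.88). Clec3b was 3.27-fold lower (2.75 to 3.91) and Dlk1, an imprinted Notch-like protein, 2.15-fold lower (2.01 to 2.31). Cdkn1a had 1.07 and 52.2 CPM, but 1 cell supplied 66.9% of its cKO UMIs. Mural markers were higher in 3 of 5 in these cells, with a median log2 ratio of 0.84. G2/M genes had a median of -0.21 (-0.28 to -0.14) and S phase genes of 0.19 (0.11 to 0.26). Cluster 11 of this class, led by Cenpf, Mki67 and Top2a, held 21 of the 99 control and 22 of the 134 cKO cells. Its share in each library also enters these medians.

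In mural-like cells, 52 in the control and 61 in the cKO library, Ccl2 was again among the highest, 3.46-fold higher (2.70 to 4.48). Hist1h2ap, a histone gene, was 5.86-fold lower (4.01 to 8.77), the mitotic kinase Aurkb 4.23-fold lower (2.64 to 6.99) and Btg2 3.17-fold lower (2.56 to 3.94). Of 43 G2/M genes 12 were lower and 0 higher, with a median of -0.41 (-0.50 to -0.32). Dissociation stress genes had a median of -0.46 (-0.58 to -0.32) in these cells. For Eln, 4.27-fold lower, 1 cell supplied 52 of the 73 control UMIs, and the cKO library had 27. Over all kept cells macrophage markers had 222 and 99.6 CPM, and other leukocyte markers 147 and 31.1 CPM.

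The hypoxia response list had a median above 0 in each class compared: the 23 genes measured in endothelial-like cells had medians of 0.53 there, 0.41 (0.30 to 0.52) in fibroblast-like, 0.47 in mural-like and 0.43 in cardiomyocyte-like cells. A different mix of male and female embryos as the whole source is argued against in fibroblast-like cells, with 0.50 in those with Xist alone and 0.33 (0.22 to 0.46) in those with Y-linked transcripts alone. In endothelial-like cells the median was 0.38 with Xist alone and 0.43 with Y-linked transcripts alone, against 0.53, so a part played by the mix is open there. The weight of deep cells as the whole source is argued against in fibroblast-like cells. Their thinned median was 0.42 (0.27 to 0.62) against 0.44 unthinned, with its lower bound above the limit of 0.22 set beforehand. The lower bound passed it in 15 of 20 draws, and with equal weight per cell, which gives each gene the level expected over draws, the median was 0.50 (0.34 to 0.56). Median depths of fibroblast-like cells were close, at 18620 and 19650 UMIs. The test therefore does not decide on depth in classes that differed more, such as mural-like cells, with 17556 and 24054 UMIs. In endothelial-like cells, with 14193 and 18616 UMIs, the hypoxia median was 0.65 in the main thinning draw. Handling or oxygen supply of each heart may differ by library, and the design confounds these with genotype.

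The p53 response list had a median of 0.69 in endothelial-like cells, with 7 of 14 members higher and 1 lower. A different mix of sexes is argued against, with medians of 0.56 (0.41 to 0.75) in cells with Xist alone and 0.80 (0.55 to 1.08) in cells with Y-linked transcripts alone. Single thinning draws did not decide on depth: the thinned median was 0.48 (0.24 to 0.91) against 0.69, draws ran from 0.22 to 0.93, and 12 of 20 had a lower bound above 0.35, the limit set for it. With equal weight per cell the median was 0.74 (0.58 to 0.92), which argues against the weight of deep cells as the whole source. A shift of the whole library cannot be told apart, because the same genes had medians of up to 0.35 (0.17 to 0.47, mural-like), 0.24 in fibroblast-like and 0.06 in cardiomyocyte-like cells.

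S phase and G2/M genes in the Npr3-high clusters had a median of 1.29 (1.19 to 1.37) over 74 genes. Cluster 13 as the whole source is argued against, since clusters 6 and 8 still gave 0.34 (0.28 to 0.47), although its 17 cells supplied most of the difference. The weight of deep cells as the whole source is argued against by a thinned median of 1.23 (1.04 to 1.38), with all 20 draws above the limit. Thinning evens out the weight of cells in the sums, so it does not decide on depth that differs with the kind of cell. Cluster 13 had a median of 22151 UMIs per cell, against 13428 in control Npr3-high cells. Doublets cannot be told apart, since only 1 called doublet could be removed, which left the median at 1.30 (1.20 to 1.38). No biological explanation was tested, since 1 library per group leaves genotype, embryo and staging confounded.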
